A study of Mus musculus with 32 samples.

How the data were processed

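RNA was measured in 32 mouse stem cell libraries, made from total RNA with the NEBNext Ultra II kit per the labels' protocols. The deposited count table holds raw counts per gene symbol for 25 of them, with whole numbers and no normalization. The aligner, counting tool, genome build and annotation behind it are not given in the sources used here, so no coordinates are printed for its genes. For the other 7 libraries, all PrES, the authors gave values in RPKM, on build mm10 per the labels. Their totals lay between 5410.4 and 11206 RPKM, lower than is usual, and 830 to 1610 genes reached 1 RPKM, so the scale of these values is uncertain and they were compared only with each other. Coordinates given for them are those of GENCODE vM21 on mm10. Their depth is unknown, as the table gives no counts. "P12" and like terms in the titles were taken as passage numbers.

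Columns of the count table were matched to the labels by group, with the replicate numbers of the column names, and those of the RPKM table by title. The columns of the count table do not name the line, and lines were not inferred from the values, so libraries of a line were not paired. The columns of the count table fall into 9 groups. Genes that 1 counting set lacks are filled with 0 in its columns, and only the 27542 genes with counts in both sets were tested, which hold between 84.3% and 97.0% of each library's counts. CPM values were computed over these genes with library sizes scaled by TMM, except that values of genes counted only in the 17-library set were computed over all genes of that set and those of sex-linked genes over all counts without TMM. Means and SDs are over libraries.

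Differences in counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization (factors 0.883 to 1.14), its filter on low counts (filterByExpr) and the quasi-likelihood test. PrES, XEN, TS and ES in FBS/L2i were compared in a fit of 18 libraries by cell type (15353 genes, 14 residual degrees of freedom). All other comparisons came from a fit of all 25 libraries by group (16011 genes, 16 residual degrees of freedom), in which groups of 2 libraries borrow their spread from the others. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 and the log2 fold change was at least 1 in size. Fold changes in the text are on the log2 scale, and their SE is the size of the log2 fold change divided by the square root of the F statistic. Against a group at 0 the fold is a lower bound, computed from 3 counts over the group. With 1 to 3 counts it is a ratio with its 95% exact Poisson interval. Floors and intervals cover counting error only. RPKM values were compared with limma 3.58.1 (trend) on log2(RPKM + 1) over genes with a mean of at least 1 RPKM, with the same thresholds.

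Gene lists (23) were fixed before the data were examined, as were the groups, tests, thresholds, the rule for naming genes and the alternatives, apart from those named below as added. Lists except the sex-linked one were tested with camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation. Of the listed genes, 2 of the 2-cell-like list are absent from the count table, and Tcstv3, Prl2c2, Dppa5a, Rhox5, Apoa2 and Spink1 are at 0 in all libraries of the 17-library set. For each comparison the text names from the 8 called genes with the largest and the 8 with the smallest log2 fold change among genes with at least 10 CPM (or RPKM) in the higher group and no overlap between the groups' libraries, leaving out placeholder symbols from the report and sex-linked genes. It also names up to 4 called members of a list by size of change, and 11 marker genes in cell type comparisons. In comparisons that coincide with the counting set, genes were taken in this order among those whose call held with the set as a term, an exception chosen after the values were seen that was not applied to members of lists and marker genes; it passed over Tmem72, Sgip1, Apof, Mrgpra6, Gkn2 and Gkn1 among others. Alternatives with the counting set as a term and within the 17-library set were also added after the data were seen.

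The axis position of a library is the projection of its log2 CPM (prior count 2) on the line from the XEN mean to the PrES CD-1 mean over genes called between them, with a library of these groups scored while left out, tested by exact two-sided permutation. Overlaps were set beside the product of the counts over the number of genes. Alternatives covered DESeq2 1.42.0 with its Wald test, its size factors in edgeR, no filter on low counts, no fold threshold, only the libraries compared, CD-1 libraries only, each library left out in turn, and for RPKM a pseudocount of 0.1, no filter, scaling to the median and only the libraries with a passage. The fits were tested on simulated data with 200 changed genes. For PrES against XEN (14873 genes) 79% of changes of 1.5 and 95% of changes of 3 on the log2 scale were called, with 5 unchanged genes called. For PrES to XEN against PrES (15443 genes) these were 62%, 82% and 7, and for the RPKM comparison (1231 genes) 95%, 100% and 1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Genes counted in only 1 of the sets were left out of all tests because their 0 values in the other set may not be measurements.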

Results

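Stem cell lines of the mouse blastocyst were profiled by RNA-seq. PrES (primitive endoderm stem) cells were derived from blastocysts on mouse embryonic fibroblast (MEF) feeders in a medium with CHIR99021 (CHIR, a GSK3 inhibitor that activates Wnt signalling), FGF4, heparin and PDGF-AA, per the labels' protocols. The primitive endoderm is the blastocyst layer that forms the endoderm of the yolk sac. XEN (extraembryonic endoderm) cells are the established endoderm line of the blastocyst, TS (trophoblast stem) cells represent the trophectoderm and ES (embryonic stem) cells the epiblast. Counts covered 25 libraries. They comprised 6 PrES libraries (4 of outbred CD-1 and 2 of the hybrid PWKB6NF1), 4 XEN libraries (2 in LIF and 2 in LIF with CHIR, from 2 lines that the titles name in both media), 6 TS libraries and 2 ES libraries in FBS/L2i. The other groups were 2 libraries of PWKB6NF1 lines after a change from PrES to XEN culture with CHIR ("PrES to XEN"), 3 XEN libraries in Basic02 with Wnt3a ("XEN Wnt3a") and 2 ES libraries in NB/L2i on gelatin. The titles give CD-1 for the TS lines and for the XEN lines in LIF media, and no strain for the ES and XEN Wnt3a lines. Each held between 10292776 and 29406378 counts. A further 7 PrES libraries were given as RPKM, 3 at passage 12, 2 at passage 38 or 41 and 2 with no passage stated. The p-values below measure only the spread between these samples.

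The count table joins 2 counting sets that were not counted alike. The XEN libraries in LIF or LIF/CHIR, the ES libraries in FBS/L2i and 2 TS libraries form an 8-library set, and the remaining 17 libraries form the other. Of 42212 genes, 6147 (the mitochondrially encoded mt-Co1 among them) had no counts in the 8-library set. Another 8523 were at 0 in all 17 libraries, including abundant ones such as the ribosomal protein genes Rpl8 and Rps14. All tests used the 27542 genes counted in both. TS libraries occur in both sets, and 697 of 10083 genes expressed in them differed by over 1 on the log2 scale between the sets. PrES against XEN, PrES against ES in FBS/L2i, both comparisons of other cultures with XEN in LIF media and the comparison of ES media therefore coincide with the counting set. Beside these, values are given with the set as a term (estimated from the TS libraries) and within the 17-library set, where XEN Wnt3a stood for XEN and ES in NB/L2i for ES.

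PrES and XEN cells, the cultured forms of the same embryonic layer, differed in pluripotency genes, which PrES cells expressed, and in basement membrane genes, which XEN cells expressed at high levels. These were the 2 lists that passed with both the preset and an estimated correlation. Pou5f1, which encodes the pluripotency factor OCT4, was at 1029.9 ± 169.9 CPM in PrES (mean ± SD, n = 6) and 0.229 ± 0.167 CPM in XEN (n = 4), a log2 fold change of 12.10 (SE 0.53, adjusted p = 3.77e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was 11.65 with the set as a term and 9.98 within the 17-library set. The 4 XEN libraries come from 2 lines but were fitted as independent, so SEs and p-values in all comparisons with them may be too small. Nanog (142 ± 210.2 against 0.21 ± 0.168 CPM) and Sox2 (65.1 ± 87.6 against 0.152 ± 0.0647 CPM), partners of OCT4 in ES cells, were also higher in PrES, by 9.44 and 8.71 on the log2 scale, but with an SD above the mean. The endoderm factors went the other way. Gata4 was at 222 ± 76.1 CPM in PrES and 973 ± 31.5 CPM in XEN (-2.15, SE 0.29, adjusted p = 8.65e-06), and it stayed lower with the set term (-1.37) and within the 17-library set (-1.41). Gata6 (-1.70, SE 0.31), Sox17 (-1.33, SE 0.31) and Foxa2 (-1.79, SE 0.29) were likewise lower in PrES and within the 17-library set (-1.70, -1.45 and -2.22), whereas none of them passed with the set term (-0.88, 1.01 and -0.71). Pdgfra, the receptor for PDGF-AA, was at 511 ± 192 and 609.5 ± 99.9 CPM and did not pass (-0.27, adjusted p = 0.513). Hnf4a (-0.92) and the trophoblast factor Cdx2 (0.51) had no call either, and Eomes was higher in PrES (4.26 against 1.17 CPM, 1.85). Hnf4a passed without PrES CD-1 replicate 2 (-1.01) or 3 (-1.02), XEN LIF/CHIR replicate 1 (-1.09) or XEN LIF replicate 2 (-1.01), and Cdx2 without the last (1.36).

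**Figure D1:**
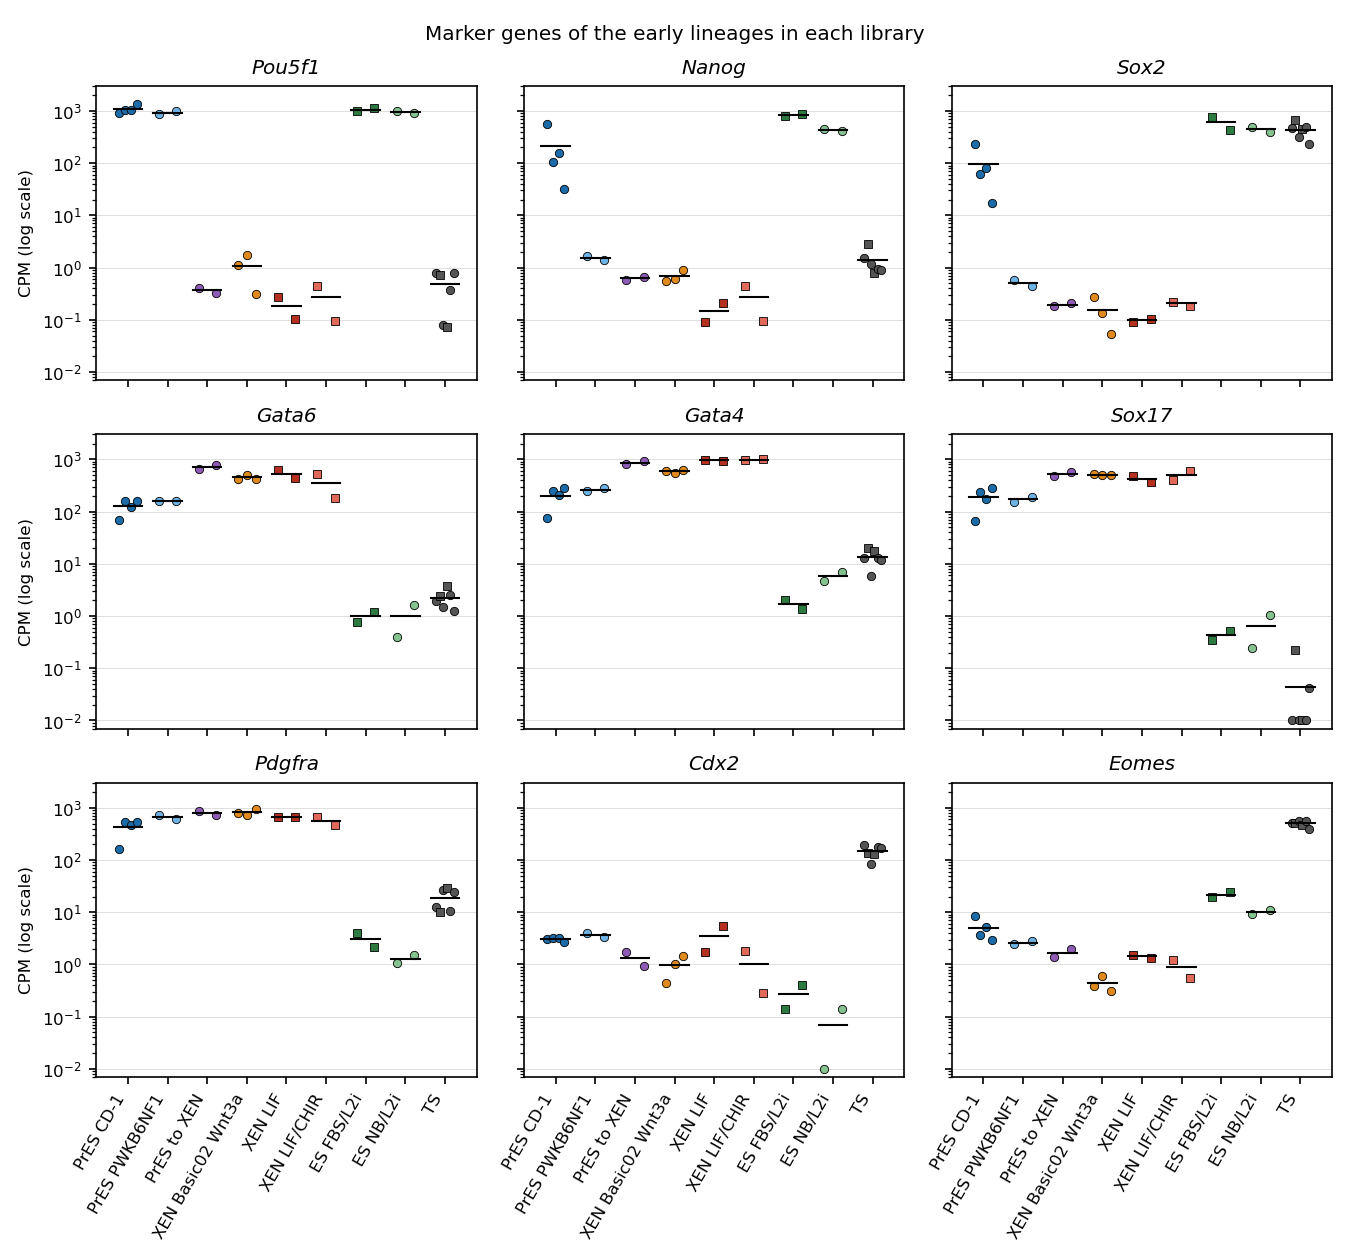
CPM per library of 9 marker genes on a log axis, in 9 groups; squares are libraries of the 8-library set, circles those of the 17-library set, black lines are group means, and values of 0 are drawn at 0.01. Pou5f1 stands at 1084 CPM in PrES CD-1, 921 in PrES PWKB6NF1 and 0.366 in PrES to XEN.

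Of the naive pluripotency list, 20 of 21 measured members were higher in PrES and 0 lower (camera, adjusted p = 1.34e-15, and adjusted p = 0.0429 with an estimated correlation). Their median log2 fold change was 7.58. With the set as a term 11 members were called higher and 0 lower, with a median of 7.85 (camera, adjusted p = 8.56e-12, and adjusted p = 0.0974 with an estimated correlation). Tdgf1, the Nodal co-receptor Cripto, and Tcl1 were at 273 ± 394 and 66.4 ± 16.1 CPM in PrES and at 0 in XEN, at least 4072-fold and 989.7-fold higher against a floor of 3 counts over the group, but neither passed with the set term. Dnmt3l, a cofactor of de novo DNA methylation, was at 115 against 1.08 CPM (6.66), and Tet2, which oxidises methylcytosine, followed (4.58). The DNA methylation list as a whole had 6 higher and 2 lower of 11 and no call. In the opposite direction, 16 of 18 basement membrane genes were lower in PrES, with a median of -2.49 (adjusted p = 7.14e-11, and adjusted p = 0.0429 with an estimated correlation). Laminin chain genes Lamc1 (832 ± 273 against 13007 ± 3467 CPM, -3.98, SE 0.25) and Lama1 (-3.65), the nidogen gene Nid1 (-4.04) and Fras1 (-4.52) led this group. Parietal endoderm genes, those of the matrix-laying endoderm of the yolk sac, were lower for 19 of 22 members (adjusted p = 9.26e-10, and adjusted p = 0.119 with an estimated correlation). Thrombomodulin (Thbd) was at 1.73 against 236 CPM (-7.09) and tissue plasminogen activator (Plat) was lower as well (-5.29), while the protease inhibitor gene Tfpi2 was higher, at 33.4 ± 29.6 CPM against 1 count over the XEN libraries (1495-fold, with a 95% counting interval of 268 to 59058).

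Lists without a call mostly held members in both directions. Primitive endoderm regulators had 4 higher and 11 lower of 21, among them Amn, an endocytic partner of cubilin (4.42), and the FGF receptor genes Fgfr1 (3.27) and Fgfr3 (-3.74). Wnt response genes had 10 higher and 1 lower of 16, with Lef1 at 9.77 CPM against 2 counts (218-fold, with a 95% counting interval of 60.5 to 1804) and Sp5 (7.00), which did not pass with the set term, among the higher (adjusted p = 0.0724, and adjusted p = 0.282 with an estimated correlation). Visceral endoderm genes had 10 higher and 8 lower of 23, with Rbp4, the retinol carrier, at 0.174 against 90.7 ± 100.3 CPM (-8.99). Imprinted genes had 12 higher and 8 lower of 26, Nodal and BMP response genes 5 higher and 3 lower of 15, trophoblast stem genes 5 higher and 4 lower of 17 and p53 targets 2 higher and 6 lower of 15. For the Nodal and BMP list the median (-0.33) and the mean (1.35) differed in sign. With the set as a term primitive endoderm regulators had 4 higher and 5 lower members, Wnt response genes 5 and 0, visceral endoderm genes 5 and 3 and p53 targets 1 and 1. The Wnt response list then passed camera with the preset correlation (adjusted p = 0.0352), but not with an estimated one (adjusted p = 0.148). Primed epiblast genes had 6 higher and 2 lower of 12, 2-cell-like genes 3 higher and 0 lower of 6, differentiated trophoblast genes 5 higher and 2 lower of 13, epithelial genes 8 higher and 4 lower of 17 and cholesterol synthesis genes 6 higher and 1 lower of 20. Amino acid and ER stress genes had 3 higher and 4 lower of 16 and FGF-ERK response genes 3 higher and 5 lower of 15. Counts adjusted over the list alone differed for 4 lists: basement membrane (1 higher, 16 lower), FGF-ERK response (3 and 4), Nodal and BMP response (6 and 3) and amino acid and ER stress (2 and 4).

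The feeder fibroblast list was higher in PrES, with 13 of 18 members called (adjusted p = 4.98e-09, and adjusted p = 0.199 with an estimated correlation), and mesenchymal genes had 7 higher and 1 lower of 14. The collagen gene Col3a1 was at 113 ± 86.9 CPM in PrES and 0 in XEN, at least 1680.0-fold higher, but lower in PrES within the 17-library set (-3.66), where the list had 1 higher and 10 lower members. The G2-M list, 1 of 18 lower here, had 18 higher members within that set, and the glycolysis and hypoxia list went from 3 to 14 higher members of 19.

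Among single genes, the largest differences were at genes silent in one culture. Stmn2, a neuronal microtubule regulator, was at 83.3 ± 82.8 CPM in PrES and 0 in XEN (at least 1242-fold; 9.68 within the 17-library set). The cytochrome gene Cyp1b1 (58.7 ± 27.6 CPM), the cadherin gene Cdh4 (44.3 ± 13.6 CPM), the dimethylglycine dehydrogenase gene Dmgdh and the endophilin gene Sh3gl2 were also at 0 in XEN. Grem1, a secreted BMP antagonist, was at 124 ± 58.2 CPM against 1 count. Cyp1b1 (125 CPM) and Grem1 (87.3 CPM) were also present in PrES to XEN, where feeder fibroblast genes such as Col3a1 (359 CPM) were found too. Whether their reads in PrES libraries come from PrES cells was not tested. Myh7, a myosin gene of heart muscle, was lower in PrES, at 0.174 ± 0.0681 against 109.7 ± 91.0 CPM (-9.25, SE 0.55, adjusted p = 1.39e-09), as were Myh6 (-9.07) and Mybpc3 (-8.75). The prostaglandin receptor gene Ptger3 (-8.91, and -10.96 within the 17-library set), the endothelial cadherin gene Cdh5 (-8.70, SE 1.08) and Nepn (-9.72) were lower too. Pagr1a was at 0 in PrES and 37.7 ± 2.05 CPM in XEN, at least 1263-fold lower. It was also called lower in PrES to XEN than in XEN, a call lost with the set term, so it may follow the counting set. In all, edgeR called 3831 genes higher and 2322 lower of 15353 tested. With the set as a term the counts were 2626 and 1945, and against XEN Wnt3a within the 17-library set they were 3643 and 3531.

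Set against ES cells in FBS/L2i, PrES cells carried the endoderm program together with an equal level of Pou5f1. Gata6 was at 138 ± 37.7 CPM in PrES (n = 6) and 0.993 ± 0.309 CPM in ES (n = 2; 7.17, SE 0.63, adjusted p = 1.50e-06). Gata4 (7.04), Sox17 (8.77), Pdgfra (7.40) and Foxa2 (7.97) were higher by similar amounts, Hnf4a by 3.46, and within the 17-library set against ES in NB/L2i all 6 were called as well (6.98, 5.16, 8.06, 8.54, 6.35 and 4.22). With the set term Hnf4a did not pass (5.93, adjusted p = 0.125). Pou5f1 stood at 1029.9 ± 169.9 and 1063 ± 120.0 CPM (-0.01, SE 0.35, adjusted p = 0.992). Nanog was at 142 ± 210.2 against 848 ± 45.9 CPM and did not pass (-2.51, adjusted p = 0.0786). Sox2 was lower in PrES (-3.16, adjusted p = 0.027), a call lost with the set term (adjusted p = 0.337) and within the 17-library set (adjusted p = 0.0563), and without ES FBS/L2i replicate 1 (-2.66) or 2 (-3.53). Nanog passed without PrES CD-1 replicate 1 (-3.77). Cdx2 was higher (3.70) and Eomes lower (-2.29). Cubn, the endocytic receptor cubilin of visceral endoderm, was at 387 ± 85.5 against 0.256 ± 0.0359 CPM (10.53, SE 0.53, adjusted p = 2.70e-09), and the water channel gene Aqp8 was higher by 11.04, though not past the test with the set term. Nostrin (8.68) followed, Clvs1 was at 11.6 CPM against 0 (at least 164-fold), Tfpi2 at 33.4 CPM against 3 counts (474-fold, with a 95% counting interval of 162 to 2298), and Cyp26a1, which degrades retinoic acid, was at 48.7 ± 50.3 CPM against 3 counts (691-fold, with a 95% counting interval of 236 to 3350.3). Lower in PrES were Olig1 and Olig2, bHLH factors at 0 in PrES and 16.5 and 15.7 CPM in ES, Crtac1 (-7.29), Atp1b2 (-6.11) and the transglutaminase gene Tgm2 (-5.92).

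Of the primitive endoderm regulators, 17 of 21 were higher than in ES and 1 lower, with a median of 6.49 (adjusted p = 2.15e-19, and adjusted p = 0.0238 with an estimated correlation). Parietal endoderm genes had 15 higher and 2 lower of 22 (adjusted p = 7.13e-09, and adjusted p = 0.314 with an estimated correlation), among them the parathyroid hormone receptor gene Pth1r (7.51) and the vitamin A transporter gene Stra6 (7.42), which did not pass with the set term (adjusted p = 0.0987). Visceral endoderm genes had 11 higher and 3 lower of 23 (adjusted p = 4.89e-04, and adjusted p = 0.37 with an estimated correlation), with the ligand gene Ihh (8.47) and the Wnt antagonist gene Dkk1 (8.18). Basement membrane genes had 9 higher and 2 lower of 18 (adjusted p = 5.37e-04, and adjusted p = 0.37 with an estimated correlation), led by Col4a1 at 2799.9 ± 807 against 59.0 CPM (5.60) and Col4a2 (4.65). Naive pluripotency genes had 0 higher and 9 lower of 21, with Fgf4 (-3.90), Klf2 (-3.57) and Prdm14 (-2.75) among the lower ones (adjusted p = 0.0273, and adjusted p = 0.65 with an estimated correlation; adjusted p = 0.0951 with the set term). None of these 3 passed with the set term, nor without ES FBS/L2i replicate 1 (-3.27, -2.74 and -2.86), and without replicate 2 Prdm14 did not (-2.62). The immediate early gene Egr1 was higher (222 against 7.07 CPM, 4.98) in an FGF-ERK list with 4 higher and 2 lower of 15. Cholesterol synthesis genes had 5 higher and 0 lower of 20 (adjusted p = 0.00644, and adjusted p = 0.65 with an estimated correlation), and the G2-M list, 2 of 18 lower, passed with the preset correlation only (adjusted p = 0.0334, and adjusted p = 0.65 with an estimated correlation) and not with the set term (adjusted p = 0.0795). The 8 lists had the same counts adjusted over the list alone. With the set term 16 primitive endoderm regulators, 11 parietal endoderm, 6 visceral endoderm and 8 basement membrane genes were higher. Of the naive pluripotency genes 1 was then higher and 3 lower. The feeder fibroblast list, with 2 higher and 4 lower of 18, did not pass, whereas against ES in NB/L2i, grown without feeders, 13 of its members were higher. In all 2014 genes were called higher and 2391 lower. The counts were 1142 and 1076 with the set term, 2660 and 2786 within the 17-library set, and 1590 lower without ES FBS/L2i replicate 1.

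The trophoblast program separated TS from PrES cells. Hand1, a trophoblast giant cell factor, was at 0.268 ± 0.123 CPM in PrES (n = 6) and 764 ± 487 CPM in TS (n = 6; -11.41, SE 0.49, adjusted p = 1.28e-11). Cdx2 (3.25 against 150.1 ± 40.7 CPM, -5.52) and Eomes (4.26 against 502 ± 61.5 CPM, -6.87), which maintain TS cells, and Elf5 (-8.90) and Gata3 (-6.83) were lower in PrES, and all 17 measured members of the trophoblast stem list were (adjusted p = 9.16e-16, and adjusted p = 5.07e-04 with an estimated correlation). Sox2, which TS cells also express, was at 65.1 ± 87.6 against 438 ± 153 CPM (-2.72). The placental prolactin family genes Prl3d1 and Prl7a1 had 1 and 2 counts over the PrES libraries and 67.7 ± 70.4 and 103 ± 156 CPM in TS, Serpinb9f was at 0 in PrES, and Tmem114 (-10.64), Duox2 (-10.35) and the metalloprotease gene Mmp9 (-10.28) were lower. Habp2, a secreted serine protease gene, was at 116 ± 51.8 CPM in PrES and 0 in TS, as were the thyrotropin-releasing hormone gene Trh (122 ± 169 CPM) and Tcl1. Klb, the co-receptor of endocrine FGFs, was at 253 ± 83.6 CPM against 2 counts over the TS libraries (11012-fold, with a 95% counting interval of 3048 to 90926). Aqp8 (12.22), Tdh (11.95), Tdgf1 (11.90) and Sox17 (11.80) followed. Pou5f1 (10.97), Nanog (6.73), Gata6 (5.97), Gata4 (4.04), Pdgfra (4.75) and Foxa2 (4.08) were higher in PrES as well.

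Naive pluripotency genes had 14 higher and 3 lower of 21 than in TS (adjusted p = 2.52e-07, and adjusted p = 0.155 with an estimated correlation), primitive endoderm regulators 15 higher and 3 lower of 21 (adjusted p = 7.59e-13, and adjusted p = 0.112 with an estimated correlation) and visceral endoderm genes 16 higher and 3 lower of 23 (adjusted p = 9.14e-05, and adjusted p = 0.155 with an estimated correlation), the last with Hnf4a at 24.4 CPM against 1 count (2123-fold, with a 95% counting interval of 381 to 83869.9) and the endocytic receptor gene Lrp2 (8.81). Parietal endoderm (14 higher and 5 lower of 22) and basement membrane genes (10 higher and 3 lower of 18) were higher as well, with adjusted p = 0.494 and 0.326 with an estimated correlation. Epithelial genes were lower for 13 of 17 members, among them the claudin genes Cldn4 (-3.65) and Cldn7 (-3.19; adjusted p = 3.63e-04, and adjusted p = 0.326 with an estimated correlation). FGF-ERK response genes had 0 higher and 11 lower of 15, with Myc (-4.75), Fosl1 (-4.24) and Dusp6 (-3.45; adjusted p = 9.14e-05, and adjusted p = 0.155 with an estimated correlation), and adjusted over the list alone 12 were lower. Primed epiblast and early mesoderm genes had 2 higher and 8 lower of 12, led by Pou3f1 (-9.67; adjusted p = 9.14e-05, and adjusted p = 0.155 with an estimated correlation). The imprinted genes Igf2 (43.5 against 2619 CPM, -5.91) and Cdkn1c (-7.32) were lower in PrES. Other lists of this paragraph had the same counts adjusted over the list alone. EdgeR called 3020 genes higher and 3290 lower, and 3128 and 3169 against the 4 TS libraries of the 17-library set.

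Genes higher in PrES than in XEN, ES and TS each numbered 627. Independent lists of these sizes would share 98.9, and 20 simulated tables with no effect gave at most 0. All 3 comparisons use the same PrES libraries, so the excess is not read as a shared effect. With the set term 284 genes passed the 3 tests, and 190 of these were among the 627. The named genes also passed within the 17-library set. Amn was at 178 ± 101 CPM in PrES and between 0.893 and 8.09 CPM in the other types. Nefl and Nefm, the neurofilament light and medium chain genes, were at 364 ± 193 and 125 ± 57.8 CPM, with Nefl at 6.80 CPM in XEN and 23.9 in ES. Npl, the sialic acid lyase gene, was at 543 ± 173 CPM against 40.7 in XEN, 10.8 in ES and 1.79 in TS. Tfpi2 (33.4 CPM), Fam181b (22.2 CPM), Pdlim4 (133 CPM) and the GABA receptor subunit gene Gabre (21.6 CPM) belonged to the same group. Il1bos (27.0 CPM) lies antisense to Il1b and is uncertain, since the strand of counting is not given in the sources used here. Of the fixed lists, Cubn, Amn, Dkk1, Tfpi2, Nkd1 and Psg17 were higher than in all 3 types and also with the set term and within the 17-library set.

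The PWKB6NF1 lines, labelled female, and the CD-1 lines, labelled male, differed within PrES, so strain and sex were not separable. Nanog was at 1.54 ± 0.168 CPM in PWKB6NF1 (n = 2) and 212 ± 232 CPM in CD-1 (n = 4; -7.17, SE 0.95, adjusted p = 1.15e-04), and Sox2 at 0.513 ± 0.11 and 97.4 ± 92.8 CPM (-7.61). The CD-1 libraries spread widely, with Nanog at 552, 107, 159 and 31.6 CPM. Pou5f1 did not differ past the test (921 ± 78.0 against 1084 ± 185 CPM, -0.28), nor did Gata6, Gata4 or Sox17. Tdgf1 (-9.00), Fgf4 (3 counts against 25.1 ± 23.9 CPM) and T, the brachyury gene of early mesoderm (1 count against 20.7 ± 28.2 CPM), were lower in PWKB6NF1, as were Trh (-9.86) and Serpina3m (-9.59, SE 1.33). Khdc3 was at 0 against 10.4 ± 6.16 CPM. Vnn1, a pantetheinase gene, was at 105 ± 5.00 against 1.58 ± 0.487 CPM (6.02, SE 0.39, adjusted p = 1.18e-08), and Pla2g7 (5.31), Trim5 (5.14) and Plxnc1 (4.66) were higher too. The pseudogene Gapdh-ps15 (1003 against 0.561 CPM) is uncertain, because it can take reads of Gapdh. Nodal and BMP response genes had 0 higher and 6 lower of 15 (adjusted p = 1.60e-04, and adjusted p = 0.0413 with an estimated correlation), with Lefty2 (-5.98) and Nodal (-5.87), and naive pluripotency genes 0 higher and 9 lower of 21 (adjusted p = 3.13e-08, and adjusted p = 0.0413 with an estimated correlation). FGF-ERK response genes had 0 higher and 5 lower of 15, with Etv5 (-4.54) and Dusp6 (-4.14; adjusted p = 3.11e-04, and adjusted p = 0.124 with an estimated correlation). Feeder fibroblast genes had 3 higher and 0 lower of 18 (adjusted p = 4.84e-04, and adjusted p = 0.464 with an estimated correlation), with Lox at 309.8 against 80.6 CPM (1.89), Fbn1 (2.04) and Col6a3 (1.96), and these 3 calls were lost without PWKB6NF1 replicate 1 (2.01, 2.08 and 2.10) or 2 (1.74, 1.98 and 1.80). That of Lox was also lost without CD-1 replicate 2 (1.86) or 4 (1.73). Adjusted over the list alone, 10 naive pluripotency genes were lower and 4 fibroblast genes higher, and the counts of the 2 other lists were the same. With the preset correlation 13 of 22 lists passed and with an estimated one 2. In all 334 genes were called higher and 736 lower in PWKB6NF1. The counts fell to 122 and 84 without PWKB6NF1 replicate 1, where Nodal (-5.53), Dusp6 (-3.91) and T (-8.44) lost their calls, and to 136 and 105 without replicate 2, where T (-11.48) and Gapdh-ps15 (10.71, and 10.88 without replicate 1) lost theirs.

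After the change of the PWKB6NF1 lines to XEN culture with CHIR, most naive pluripotency genes fell and most basement membrane and parietal endoderm genes rose, a comparison within the 17-library set. Pou5f1 fell from 921 ± 78.0 CPM in PrES PWKB6NF1 (n = 2) to 0.366 ± 0.0474 CPM (n = 2; -11.25, SE 0.71, adjusted p = 2.55e-09) and the pluripotency factor gene Esrrb from 116 ± 5.11 to 0.174 ± 0.0109 CPM (-9.31, SE 0.45). Tfpi2, Tcl1 and Tktl2 were left with 1 count each, Dppa3 with 2 and Fkbp6 with 3 over both libraries, from 71.1 CPM for Tfpi2 and 35.5 CPM for Dppa3, and Pramel7 was at 0. Nanog, already at 1.54 ± 0.168 CPM in these PrES lines, did not pass (-1.28, adjusted p = 0.322). Gata6 rose from 159.8 ± 4.10 to 728 ± 95.4 CPM (2.20, SE 0.49, adjusted p = 0.00138), and Gata4 (1.72), Sox17 (1.62) and Foxa2 (2.24) rose with it, whereas Pdgfra had no call (0.27). Cdx2 fell (-1.44, adjusted p = 0.0486), a call lost whichever of the 4 libraries was left out (from -1.90 to -1.10). The call of Sox17 was lost without PrES PWKB6NF1 replicate 1 (1.48) or PrES to XEN replicate 2 (1.47). Tek, the angiopoietin receptor gene, rose from 0.284 to 181 ± 59.2 CPM (9.30, SE 1.19, adjusted p = 7.51e-06) and Cdh5 from 1 count to 116 ± 34.6 CPM (4243-fold, with a 95% counting interval of 762 to 167584). Parm1 (8.74) and the gastrokine gene Gkn2 (3 counts to 74.1 ± 60.5 CPM) rose, as did Igsf1 and Fras1 from 1 count each, and Pcdhga10 and C2cd4b from 0.

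Naive pluripotency genes fell for 13 of 21 members and rose for 1 (adjusted p = 1.38e-16, and adjusted p = 0.00378 with an estimated correlation). Basement membrane genes rose for 15 of 18, with a median of 2.28 (adjusted p = 2.03e-09, and adjusted p = 0.068 with an estimated correlation): Col4a2 reached 20915 ± 2535 from 1175 CPM (4.17), Lamc1 19865 from 1166 CPM (4.11) and Nid1 2253 from 123 CPM. Parietal endoderm genes rose for 14 of 22 (adjusted p = 3.48e-06, and adjusted p = 0.281 with an estimated correlation), with Thbd (6.78) and the activin antagonist gene Fst (4.63). Cholesterol synthesis genes fell for 17 of 20, by a median of -1.95 (adjusted p = 1.06e-11, and adjusted p = 0.264 with an estimated correlation), among them the squalene synthase gene Fdft1 (302 to 24.2 CPM), Idi1 (-3.50) and Fdps (-3.28). Amino acid and ER stress genes rose for 9 of 16 and fell for 1 (adjusted p = 0.0069, and adjusted p = 0.623 with an estimated correlation), with Trib3 (3.37), Atf5 (3.34) and Phgdh (2.42). FGF-ERK response genes, including the ERK phosphatase gene Dusp6 (3.72) and Etv5 (2.38), rose for 8 of 15 (adjusted p = 0.0284, and adjusted p = 0.425 with an estimated correlation). The G2-M list fell for 4 of 18 members, Cenpf (-1.14) among them (adjusted p = 0.0069, and adjusted p = 0.776 with an estimated correlation). Adjusted over the list alone, 14 naive pluripotency genes fell, and 17 basement membrane, 15 parietal endoderm and 10 amino acid and ER stress genes rose. Single members of other lists also moved, with Dnmt3l (-8.43), Amn (-5.97), Fgfr2 (-3.58) and the E-cadherin gene Cdh1 (-2.71) falling and Fgfr3 (3.66), Rbp4 (7.17) and the imprinted Plagl1 (5.54) rising. EdgeR called 2615 genes higher and 1890 lower after the change.

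Compared with XEN in LIF media, the changed lines had no call at any of the 4 endoderm factors named above: Gata6 was at 728 ± 95.4 against 442 ± 191 CPM (0.72), and Gata4 (-0.21), Sox17 (0.16) and Foxa2 (0.49) did not pass. The changed lines are of PWKB6NF1 and these XEN lines of CD-1, so strain, line and counting set coincide in this comparison and were not separable. Medium differs too, since both changed lines had CHIR and only part of the XEN libraries did. Wnt response genes are therefore not separable from CHIR, and Axin2 ranged from 0.904 to 9.98 CPM over the XEN libraries. Foxa2 passed with the set term (1.57), and Gata6 passed without XEN LIF/CHIR replicate 1 (1.20). Pou5f1, at 0.366 ± 0.0474 against 0.229 ± 0.167 CPM, did not pass either (0.67). Basement membrane genes had 1 higher and 1 lower of 18 and parietal endoderm genes 1 higher and 2 lower of 22, with no call for either list. Feeder fibroblast genes were higher in the changed lines for 16 of 18 members, with Col3a1 at 359 ± 345 CPM, Thy1 at 73.3 ± 43.5 CPM and Ptx3 at 41.3 ± 22.4 CPM against 0 in XEN (adjusted p = 1.67e-16, and adjusted p = 0.288 with an estimated correlation). Mesenchymal genes had 9 higher and 0 lower of 14 (adjusted p = 1.34e-05, and adjusted p = 0.288 with an estimated correlation), Wnt response genes 5 higher and 0 lower of 16, among them Axin2 (3.47; adjusted p = 0.0419, and adjusted p = 0.288 with an estimated correlation), and imprinted genes 11 higher and 3 lower of 26, among them Meg3 (8.72; adjusted p = 0.00303, and adjusted p = 0.288 with an estimated correlation). Lower were G2-M genes (12 of 18, Cdc20 -1.57; adjusted p = 1.57e-11, and adjusted p = 0.288 with an estimated correlation), cholesterol synthesis genes (8 of 20, Dhcr24 -1.99; adjusted p = 1.34e-05, and adjusted p = 0.483 with an estimated correlation) and glycolysis genes (9 of 19; adjusted p = 5.09e-06, and adjusted p = 0.3 with an estimated correlation). Of the last, Eno1 was lower (-2.70; -1.67 with the set term). When adjusted over the list alone, 10 mesenchymal genes and 7 Wnt response genes were higher, 10 glycolysis genes lower, and 0 parietal endoderm genes higher and 1 lower. The immune factor gene Irf4 was at 0.179 against 34.9 CPM (-7.58; -8.01 with the set term), and the surface protein gene Cd200 (-5.32) and the anion transporter gene Slco3a1 (-5.84) were lower. In all 3384 genes were called higher and 956 lower. With the set term 2177 were higher, and 2050 when only the libraries compared were fitted.

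The change of the lines overlapped with the difference between XEN and PrES CD-1, a comparison with no library in common. Of 2467 genes that rose, 1317 were also higher in XEN than in PrES CD-1, where independent lists would share 366. Of 1835 that fell, 989 were lower in XEN, against 471 for independent lists, and 235 genes went opposite ways. With XEN Wnt3a within the 17-library set, 1976 of 2899 and 1489 of 2084 genes were shared. On an axis from the XEN mean (0) to the PrES CD-1 mean (1) over 6113 genes, PrES PWKB6NF1 lay at 0.827 ± 0.0178 (n = 2), PrES to XEN at 0.454 ± 0.0335 (n = 2) and XEN Wnt3a at 0.388 ± 0.0608 (n = 3). With the set effect removed, PrES to XEN lay at 0.482 and XEN Wnt3a at 0.393. The XEN and PrES CD-1 ends differ in counting set and in feeder fibroblast genes as well as in cell type. A position on this axis therefore does not measure how far a line has changed. With XEN Wnt3a as the 0 end, PrES to XEN lay at 0.275 ± 0.0126. The exact two-sided permutation p of PrES to XEN against PrES PWKB6NF1 was 0.333, against XEN 0.133, of PWKB6NF1 against CD-1 0.133 and of XEN Wnt3a against XEN 0.0571, each the smallest that so few libraries allow, and PrES to XEN against XEN Wnt3a gave an exact p of 0.4, where 0.2 is the smallest. The 5 p-values were not below 0.05 and were not adjusted. In tests against XEN or CD-1, these libraries also define the axis and its genes, so part of the separation is built in and nothing is concluded from it.

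**Figure D2:**
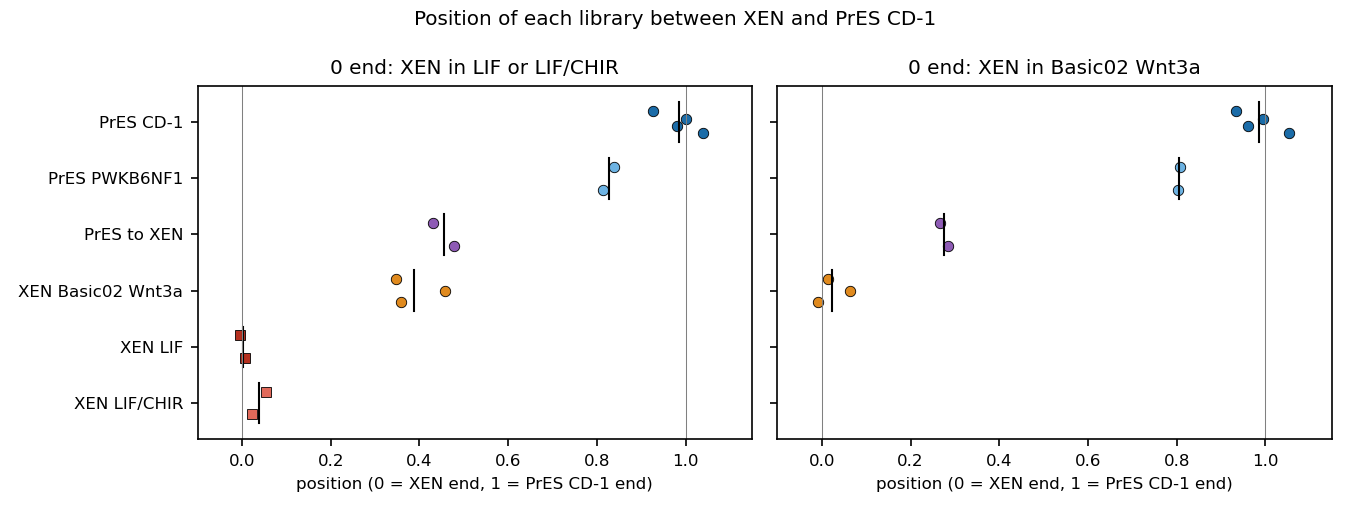
Position of each library on the axis between XEN (0) and PrES CD-1 (1), with no unit, by group; the 0 end is XEN in LIF or LIF/CHIR on the left and XEN in Basic02 Wnt3a on the right, squares and circles are libraries of the 8-library and 17-library sets, and lines are group means. PrES to XEN libraries lie between 0.431 and 0.478 on the left and between 0.266 and 0.284 on the right.

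XEN cells in Basic02 with Wnt3a, set against PrES within the 17-library set, had lower pluripotency genes and higher levels of 4 endoderm factors. Pou5f1 was at 1.05 ± 0.714 CPM in XEN Wnt3a (n = 3) and 1029.9 ± 169.9 CPM in PrES (n = 6; -9.97, SE 0.54, adjusted p = 1.03e-11), and Nanog (-5.90) and Sox2 (-6.74) were lower too. Gata6 (1.71), Gata4 (1.41), Sox17 (1.45) and Foxa2 (2.22) were higher than in PrES, and Cdx2 (-1.76) and Eomes (-3.25) lower. The gastrokine genes Gkn1 (564 ± 116 against 0.11 CPM, 12.32) and Gkn2 (773 ± 72.5 CPM against 3 counts), Ptger3 (219 ± 32.1 against 0.103 CPM, 11.02, SE 0.46, adjusted p = 3.55e-13) and Cdh5 (9.28) stood out. The yolk sac endoderm gene Afp averaged 110.4 ± 163 CPM, and Steap4 30.9 ± 44.3 CPM. Lower than in PrES were Nefl (0 against 364 ± 193 CPM), Tcl1 and the nuclear receptor gene Nr0b1 (1 count each) and Tdh (-10.90). Rpl10l, a retrogene copy of Rpl10, and Usp26 were at 0 in XEN Wnt3a, and Rpl10l is uncertain because it can share reads with Rpl10.

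All 18 genes of the G2-M list were lower in XEN Wnt3a than in PrES, by a median of -2.91 (adjusted p = 1.78e-21, and adjusted p = 0.0435 with an estimated correlation). The topoisomerase gene Top2a was at 71.0 ± 21.4 against 872 ± 174 CPM (-3.63) and the cyclin B gene Ccnb1 at 30.5 against 339 CPM (-3.44). In the same comparison feeder fibroblast genes had 11 higher and 1 lower of 18 and no list call, with Col3a1 at 1453 ± 1805 against 113 ± 86.9 CPM (3.92). The G2-M list was also lower than in XEN in LIF media for all 18 members, by a median of -3.26 (adjusted p = 1.42e-43, and adjusted p = 0.00339 with an estimated correlation), and by -3.19 with the set term, with Mki67 at 41.2 against 418 CPM. Glycolysis and hypoxia genes were lower than in PrES for 13 of 19 members (adjusted p = 1.02e-04, and adjusted p = 0.403 with an estimated correlation), among them Pfkp (-4.74), Pdk1 (-3.08) and the lactate dehydrogenase gene Ldha (163 against 1117 CPM). Against XEN 15 of 19 were lower (adjusted p = 2.88e-11, and adjusted p = 0.204 with an estimated correlation), with the pyruvate kinase gene Pkm at -3.54 and -3.34 with the set term. Naive pluripotency genes were lower than in PrES for 19 of 21 members (adjusted p = 1.98e-13, and adjusted p = 0.0131 with an estimated correlation). Basement membrane genes were higher for 15 of 18 (adjusted p = 4.34e-07, and adjusted p = 0.109 with an estimated correlation), with Nid1 at 5.97 and Lamc1 at 4.74, and parietal endoderm genes for 17 of 22 with 2 lower (adjusted p = 3.97e-06, and adjusted p = 0.243 with an estimated correlation), Thbd by 8.94. p53 targets had 7 higher and 0 lower of 15 and no list call, with Cdkn1a at 358 against 111 CPM. These lists had the same counts adjusted over the list alone. EdgeR called 3712 genes higher and 3466 lower than in PrES.

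Against XEN in LIF media, XEN Wnt3a had no call at Gata6, Gata4, Sox17, Foxa2, Hnf4a or Pdgfra, and other endoderm genes were called in both directions. Foxa2 passed with the set term (1.52). Pou5f1 was higher at a low level (1.05 against 0.229 CPM, 2.14), a call lost with the set term (adjusted p = 0.232) and without XEN Basic02 Wnt3a replicate 2 (1.63). Eomes was lower (0.435 against 1.17 CPM, -1.41), except without XEN LIF/CHIR replicate 1 (-1.10, no call). Nanog, Sox2 and Cdx2 had no call, but Cdx2 gained one without XEN LIF/CHIR replicate 2 (-1.41) or XEN LIF replicate 1 (-1.29). Sox7 was at 14.4 ± 5.77 against 119 ± 75.3 CPM (-3.07, SE 0.51, adjusted p = 4.57e-05), and Cubn (-2.51) and Lrp2 (-2.50) fell with it, although with the set term Sox7 (-2.15, adjusted p = 0.0748) and Cubn (-1.54, adjusted p = 0.182) did not pass. Primitive endoderm regulators had 3 higher and 5 lower of 21 and visceral endoderm genes 5 higher and 8 lower of 24, with no call for either list. With the set term the former had 4 higher and 2 lower and the latter 1 higher and 5 lower. Emb was at 1.04 against 243 ± 71.4 CPM (-7.95, SE 0.43, adjusted p = 8.72e-11; -8.01 with the set term), and Tfec (-7.18), Ak4 (-6.57), the surface antigen gene Cd24a (-6.17) and the Fc receptor gene Fcgr3 (-6.03) were lower as well, with Irf4 at 3 counts. Feeder fibroblast genes were higher for 16 of 18 members (adjusted p = 8.20e-10, and adjusted p = 0.304 with an estimated correlation). Col3a1 was at 1453 ± 1805 CPM and the matrix protein gene Prelp at 87.4 CPM against 0 in XEN, and Thy1 was at 33.5 CPM against 0. Grip2, which is on no list, was at 38.2 ± 1.23 CPM here, 34.6 CPM in PrES to XEN and 31.0 CPM in ES in NB/L2i, against 0 in XEN and 0.469 CPM in ES in FBS/L2i, so in these groups it followed the counting set. With the set term, estimated from the TS libraries, Grip2 kept its call in PrES to XEN against XEN (11.93) and between the ES media (5.97). Mesenchymal genes had 9 higher and 0 lower of 14 (adjusted p = 0.0146, and adjusted p = 0.762 with an estimated correlation) and imprinted genes 12 higher and 3 lower of 26, with Igf2 (6.29) and Meg3 (9.19; adjusted p = 0.0281, and adjusted p = 0.607 with an estimated correlation). FGF-ERK response genes had 3 higher and 10 lower of 15, with Etv4 (-4.25) and Spry4 (-4.15) lower (adjusted p = 0.00193, and adjusted p = 0.204 with an estimated correlation), a call lost with the set term (adjusted p = 0.0874, 6 lower), and cholesterol synthesis genes 7 higher and 1 lower of 20, with Ldlr (2.06) and Dhcr24 (2.01; adjusted p = 0.04, and adjusted p = 0.882 with an estimated correlation). The Wnt target Axin2 was higher (1.68) and Tcf7 lower (-3.54), in a list with 3 higher and 2 lower of 16 and no call, and the call of Axin2 was lost without XEN Basic02 Wnt3a replicate 2 (0.91). None of these counts moved when adjusted over the list alone. In all 3992 genes were called higher and 2102 lower, and 2731 and 1836 with the set term. The median log2 fold change of all genes was 0.24 here and 0.19 for PrES against XEN, and the changes are relative to it.

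**Figure D3:**
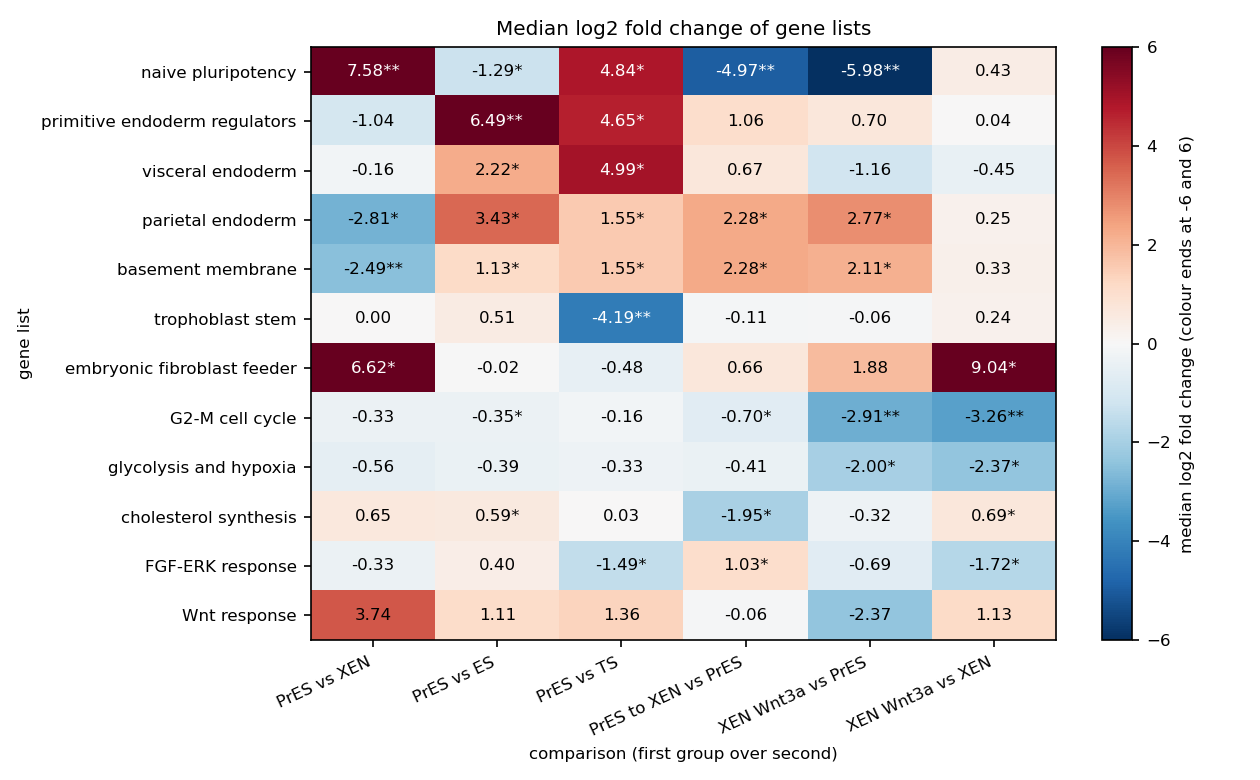
Median log2 fold change of 12 gene lists (vertical) in 6 comparisons (horizontal) as a heat map, with genes of 0 counts in a group at their bound and colours ending at -6 and 6; 1 star marks adjusted p below 0.05 by camera with the preset correlation, and 2 stars also with an estimated one. Naive pluripotency stands at 7.58 for PrES against XEN and at -4.97 for PrES to XEN against PrES.

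Addition of CHIR to XEN cultures in LIF gave no call in an unpaired fit. The titles name the same 2 lines in both media, but the columns do not name them, so the difference between the lines is part of the spread. EdgeR's quasi-likelihood test called 0 genes higher and 0 lower between XEN LIF/CHIR (n = 2) and XEN LIF (n = 2), with 911 genes at an unadjusted p under 0.05, while DESeq2 called 12 and 4. Without XEN LIF/CHIR replicate 1 edgeR called 63 and 41. Cholesterol synthesis genes (adjusted p = 1.23e-07, and adjusted p = 0.744 with an estimated correlation), amino acid and ER stress genes (adjusted p = 1.77e-04, and adjusted p = 0.744 with an estimated correlation) and glycolysis genes (adjusted p = 0.0134, and adjusted p = 0.76 with an estimated correlation) were higher as lists with the preset correlation, with medians of 0.54, 0.48 and 0.29 and no member called. Adjusted over the list alone, 1 gene of each of the first 2 lists and 1 Wnt response gene were called higher.

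ES cells in NB/L2i on gelatin (n = 2) and in FBS/L2i on MEF feeders (n = 2) had like levels of Pou5f1 (-0.06, adjusted p = 0.954), and Nanog (433 against 848 CPM, -0.87, adjusted p = 0.465) and Sox2 (-0.35) did not pass. The titles name the same 2 male lines in both media, but the columns do not name them, so the libraries were fitted unpaired. Gata4 was higher in NB/L2i (5.88 against 1.70 CPM, 1.87, adjusted p = 0.0162), a call lost without ES FBS/L2i replicate 2 (1.64) or ES NB/L2i replicate 2 (1.57). Feeder fibroblast genes were lower for 13 of 18 members, by a median of -5.07 (adjusted p = 8.95e-21, and adjusted p = 0.0983 with an estimated correlation), with Lox at 3 counts against 169.5 CPM and Col1a2 lower (-9.86). The biglycan gene Bgn (-10.93), the smooth muscle actin gene Acta2 (3 counts against 189.7 ± 216 CPM), Tnc (1 count against 70.4 CPM) and Cav1 and Wisp2 (0 against 32.5 and 28.2 CPM) were lower too. Mesenchymal genes had 0 higher and 6 lower of 14 (adjusted p = 1.38e-04, and adjusted p = 0.442 with an estimated correlation), parietal endoderm genes 0 higher and 6 lower of 22 (adjusted p = 0.00434, and adjusted p = 0.531 with an estimated correlation), glycolysis genes 0 higher and 5 lower of 19 (adjusted p = 5.67e-04, and adjusted p = 0.531 with an estimated correlation) and Nodal and BMP response genes 0 higher and 3 lower of 15, with Id3 at -5.16 (adjusted p = 0.0284, and adjusted p = 0.442 with an estimated correlation; adjusted p = 0.31 with the set term). Adjusted over the list alone, 15 fibroblast, 9 mesenchymal, 7 parietal endoderm and 6 glycolysis genes were lower. With the set term 12 fibroblast, 3 mesenchymal, 4 parietal endoderm and 1 glycolysis genes were lower, and these lists still passed with the preset correlation only. Pigp was higher, at 1019 against 19.5 CPM (5.81, and 5.84 with the set term), and Grip2 by 6.21 (5.97 with the set term). In other groups Grip2 followed the counting set as well, though its call held with the set term here. In all 673 genes were called higher and 815 lower. With the set term 265 were higher, and the counts were 239 and 466 without ES FBS/L2i replicate 2, 384 and 341 without ES NB/L2i replicate 1, and 376 and 424 without ES NB/L2i replicate 2.

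PrES lines at passage 38 or 41 (n = 2) were set beside other lines at passage 12 (n = 3) in the RPKM table, so line and passage were not separable. The titles of these 5 libraries give no sex, though the line names of passage 38 and 41 are labelled male in other samples. Sex-linked genes differed between single libraries, as given below, so sex may differ with passage and was not separable either. Differences are on the log2(RPKM + 1) scale, which understates changes of low genes, and were tested with limma. Spp1, the osteopontin gene (mm10 chromosome 5, 104435118 to 104441050), was higher at late passage, at 16.9 ± 0.0226 against 6.78 ± 0.955 RPKM (difference 1.21, SE 0.20, adjusted p = 0.0263). Its call was lost without replicate 4, 5, 6 or 7 of this table (differences of 1.11, 1.24, 1.21 and 1.22). Erdr1 was lower, at 6.48 against 52.3 ± 11.9 RPKM (-2.81). It lies in the pseudoautosomal region, which the assembly covers poorly, and is uncertain. Mid1 (-1.43), which spans the border of that region and is uncertain for the same reason, and Mrgpra6 (-1.42) were lower too. Both libraries with no passage stated held Spp1 at 15.6 and 17.9 RPKM and Erdr1 at 1.80 and 4.29 RPKM, and the first of them is of the same line as the library at passage 38. Pou5f1 was at 6.65 ± 0.112 against 9.22 ± 2.17 RPKM and did not pass (-0.39, adjusted p = 0.445), nor did Gata4 (0.15), Gata6 (-0.15) or Pdgfra (-0.20). Col4a1 (mm10 chromosome 8, 11198423 to 11312826) was at 7.80 ± 0.303 against 13.8 ± 0.449 RPKM (-0.75, adjusted p = 0.0763). None of the 14 measured basement membrane genes was called (median -0.25), nor any member of the other lists over all genes, and 1 visceral endoderm gene was called adjusted over the list alone. In all 4 genes were called higher and 12 lower of 1231, with 188 at an unadjusted p under 0.05. Leaving out single libraries gave from 0 to 8 higher and from 6 to 18 lower, with 0 higher without replicate 4 or replicate 5 of this table (7 and 6 lower), 1 without replicate 3 or 6 and 8 without replicate 7.

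Sex-linked genes were set beside the sex in the titles. The CD-1 PrES libraries, labelled male, had Xist between 7.49 and 10.0 CPM and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at 257 to 272 CPM in sum. The PWKB6NF1 libraries, labelled female, had Xist at 1952 and 1882 CPM and Y-linked genes at 38.8 and 38.6 CPM in sum. The titles name a male and a female XEN line in each medium. XEN LIF/CHIR replicate 1 and XEN LIF replicate 2 had Xist at 239.7 and 429.9 CPM and Y-linked genes at 0.289 and 0.0901 CPM. XEN LIF/CHIR replicate 2 and XEN LIF replicate 1 had Xist at 0.162 and 0.32 CPM, but Y-linked genes at only 0.811 and 3.84 CPM, against 208 and 202 CPM in the ES libraries of the same counting set, labelled male. Among TS libraries, the one in the column of male replicate 3 had Xist at 447 CPM and Y-linked genes at 9.48 CPM, and the one of female replicate 2 had 16.5 and 122 CPM, both against the sex in the column name. TS libraries were used as 1 group, so no comparison rests on these labels. In the RPKM table, Xist was at 0.944, 0.38 and 2.09 RPKM and the Y-linked genes at 0.161, 1.43 and 0.219 RPKM in sum at passage 12 (replicates 3 to 5), against 0.355 and 0.333 and 0.301 and 0.431 RPKM at passage 38 and 41, so single libraries also differed in sex-linked genes, which the fit did not take into account.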

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

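No test of an explanation was run for the results in this part, and Gm42860 and the other genes counted in 1 set were looked at only after the counting sets had been seen. Pdgfra, which encodes the PDGF-AA receptor, was at 459.9 CPM in XEN LIF/CHIR replicate 2, far from the other 3 XEN libraries, the nearest of which had 653 CPM. It was the only one of 28 groups of values set apart in this way, and chance sets apart about 1 in 20 groups.

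The placeholder gene Gm42860, counted in the 17-library set only, was the most abundant gene in 5 of the 6 PrES libraries, with a mean of 32329 CPM, and stood at 37289 ± 10739.5 CPM in PrES CD-1 (n = 4) and 22410.2 ± 7785 CPM in PrES PWKB6NF1 (n = 2). No other library of that set exceeded 8558 CPM: PrES to XEN averaged 5872, TS 6088, XEN Wnt3a 4688 and ES in NB/L2i 66.7 CPM. Gm29084 went the same way, with 15011 CPM in PrES and at most 3807 CPM elsewhere. These genes have no values in the 8-library set, and the annotation behind the count table is not given in the sources used here, so reads shared with a similar locus were not tested and the values are uncertain.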

How the results depend on the processing

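Alternatives with the counting set as a term, within the 17-library set or with all its genes, and XEN Wnt3a in place of XEN were chosen after seeing the data. Named genes that reversed did so within the 17-library set, where other cultures stand for XEN and ES: in PrES against XEN Col3a1 (-3.66), Plk1 (2.11), Thy1 (-1.14), Col5a1 (-1.39) and Tgfbi (-2.17), and in PrES against ES Npffr1 (1.48), Synb (-1.26) and Serpine1 (1.65). Culture and counting set both change there. With the set as a term Col3a1, Thy1, Tgfbi, Plk1 (-1.12) and Col5a1 (7.21) kept direction and call, as did Npffr1 (-2.68) and Serpine1 (-4.22), and Synb did not (-1.77). Kept calls do not rule out the counting set, since Grip2 followed the set and still kept its calls with the term. For Synb the cause was not tested. Over all genes, calls of opposite sign there numbered 341 for PrES against XEN, 87 against ES and 3 against TS. With the set as a term they numbered 13, 8 and 5, and 7 for PrES to XEN and 21 for XEN Wnt3a against XEN and 6 for the ES media. Within the 17-library set 514 values of named genes kept direction and call and 52 lost the call, and 3531 genes were lower in PrES than in XEN Wnt3a. With the set as a term 1142 genes were higher and 1076 lower in PrES than in ES, 2177 higher in PrES to XEN than in XEN, 265 higher in ES in NB/L2i than in FBS/L2i and 284 higher in PrES than in all 3 types. The cause was not tested. Of named values 769 stayed and 137 lost the call. With no fold threshold, which admits smaller changes, the counts were 4051 lower in PrES than in XEN, 3184 higher than in ES, 5173 higher than in TS, 3216 lower in PrES to XEN than in PrES, 2733 lower than in XEN, 3789 lower in XEN Wnt3a than in XEN, 1023 higher in ES in NB/L2i, 572 higher in PWKB6NF1 and 7 higher at late passage, with overlaps of 2023 and 1958. With only the libraries compared, 2050 genes were higher in PrES to XEN than in XEN, 511 higher in PWKB6NF1, and 7 higher and 20 lower at late passage. Fewer libraries then set the spread. Over all genes of the 17-library set 691 were higher in PWKB6NF1. DESeq2 called 12 higher and 4 lower in XEN LIF/CHIR and kept 886 named values, losing 17. Its size factors kept 901 and lost 6. The passage comparison had 1 gene higher with a pseudocount of 0.1, and 0 higher and 3 lower with no filter, where more genes were tested (limma; 3502 at an unadjusted p under 0.05). XEN Wnt3a in place of XEN gave overlaps of 1976 and 1489 and axis positions of 0.805 for PWKB6NF1 and 0.275 for PrES to XEN, and removal of the set effect gave 0.848 for PWKB6NF1. For these the cause was not tested. With an estimated correlation 161 list results stayed and 59 lost the call.

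With 1 library left out, counts higher and lower ranged from 3586 to 3883 and 2155 to 2345 for PrES against XEN, 1492 to 2185 and 1590 to 2813 against ES (1590 without ES FBS/L2i replicate 1), and 2929 to 3141 and 3047 to 3404 against TS. For PrES to XEN they were 1824 to 2214 and 1590 to 1666 against PrES and 2673 to 3384 and 656 to 951 against XEN. For XEN Wnt3a they were 3696 to 3998 and 1956 to 2092 against XEN and 3501 to 3703 and 3252 to 3511 against PrES. XEN LIF/CHIR gave 0 to 63 and 0 to 41 (the highest without XEN LIF/CHIR replicate 1). ES media gave 239 to 657 and 341 to 745, with 239 and 466 without ES FBS/L2i replicate 2, 384 and 341 without ES NB/L2i replicate 1 and 376 and 424 without ES NB/L2i replicate 2. PWKB6NF1 against CD-1 gave 122 to 285 and 84 to 917, with 122 and 84 without PWKB6NF1 replicate 1 and 136 and 105 without replicate 2. The passage comparison gave 0 to 8 and 6 to 18, with 1 and 8 genes without replicate 3, 0 and 7 without 4, 0 and 6 without 5, 1 and 18 without 6 and 8 and 10 without 7. Genes higher in PrES than in all 3 types numbered 572 to 685, and overlaps 1072 to 1187 and 793 to 855. Axis positions were 0.8 to 0.848 for PWKB6NF1, 0.431 to 0.478 for PrES to XEN and 0.353 to 0.408 for XEN Wnt3a. A group left with 1 library was assumed to vary like the others. Of named values 6256 stayed, 467 lost and 12 gained a call. No paired analysis was possible because the columns do not name the line and no line was inferred from the values. The line as a block, XEN media summed per line and displacement from one XEN line were planned and not run for the same reason, and one XEN medium was used as the 0 end in place of the last. At 10292776 to 29406378 counts per library, genes at 0 to 3 counts over a group have bounds or wide intervals only.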

Other observations

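All tests of explanations for the fibroblast genes and for Nanog in this part, and the set as a term, were chosen after the result was seen. For the splits and the test of the counting set on all genes called between PrES and XEN, predictions were written before their results. The latter test uses the comparison within the 17-library set, which was itself added after the data were seen. Endoderm products differed between single libraries of a culture. Afp, a secreted protein of visceral endoderm, was at 298 CPM in XEN Wnt3a replicate 3, 11.3 CPM in replicate 1 and 21.5 CPM in replicate 2, and Ttr, the thyroxine carrier of the yolk sac, was at 84.9, 70.8 and 29.5 CPM. The basement membrane gene Col4a1 stood at 32436, 35089 and 33456 CPM in the same order, and it was the most abundant gene in every XEN, XEN Wnt3a and PrES to XEN library. Mitochondrially encoded genes have values in the 17-library set only, where mt-Co1 averaged 20679 ± 627 CPM in PrES CD-1 (n = 4), 10426 ± 335 in PrES PWKB6NF1 (n = 2) and 4805 ± 377 in PrES to XEN (n = 2). mt-Nd4 was at 3819, 4133 and 2514 CPM in these groups.

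Feeder fibroblast genes were higher in PrES, PrES to XEN and XEN Wnt3a libraries than in XEN in LIF media, and Col1a1 reached 6017 CPM in XEN Wnt3a replicate 2. The counting set argues in the wrong direction, since the list was lower in TS libraries of the 17-library set than in those of the 8-library set (median log2 difference -0.3642). Reads from MEF feeders are a candidate source. Of these groups only XEN Wnt3a has feeders in its titles, and the protocols place the derivation of both PrES and XEN lines on feeders. The titles of TS and of ES in FBS/L2i name MEF feeders as well. The list's profile was alike between the 19 libraries that hold it (median r 0.8886 across its 18 genes, which are not independent, lowest pair 0.651), and ES cells on gelatin had a median of 0.156 CPM. No other list was set beside it, so the likeness of profiles does not tell feeders from another source of these genes. Y-linked genes summed to 38.8 and 38.6 CPM in PrES PWKB6NF1, labelled female, and to 35.4 and 15.3 CPM in PrES to XEN. XEN libraries with Xist in LIF media had 0.289 and 0.0901 CPM. Cells of a female line carry no Y-linked genes, which argues against such cells as the only source of reads in these PWKB6NF1 libraries. The counting sets differ here too, and these genes are not on the list. For the fibroblast genes, fibroblast-like cells arising within the cultures stay open, as untested.

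Nanog and Sox2 were higher in PrES CD-1 replicate 1 than in the other PrES libraries. Reads from ES cells would raise ES genes by a common share of their ES level, but the median gain over 379 genes was 20.13% of the level in ES in NB/L2i (quartiles 8.85% and 33.9%) against 105% for Nanog, 39.95% for Sox2 and 12.1% for Fgf4, which argues against them as the whole cause. T was at 62.6 CPM there and 0.739 CPM in those ES cells. Fewer endoderm-like cells in that culture may account for it, as 391 endoderm genes were lower than in replicates 2 to 4 by a median log2 difference of -0.9358 (quartiles -1.36 and -0.49), 88.0% of them lower. A change of state within the cells stays open, as untested.

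Of 6153 genes called between PrES and XEN, 59.91% had the same direction and at least a 2-fold difference against XEN Wnt3a within the 17-library set, 430 had the opposite direction by as much and 106 were not tested there. With the set as a term, estimated from the TS libraries, 3791 of the called genes kept direction and call. A kept call does not rule out the counting set, since Grip2 followed the set and still kept its calls with the term. Between XEN Wnt3a and XEN the G2-M list had a median of -3.19 and 18 lower members with the term and the fibroblast list 16 higher members. The term assumes that the sets differ in XEN cells as they do in TS cells. Neither test held for 1137 genes, for which counting set and culture cannot be told apart, because no XEN library in LIF media lies in the 17-library set. Other splits of the libraries were counted for 5 comparisons, each fitted on its own libraries, and in each 1 split, the real one, gave as many genes. PrES against TS gave 5097 genes in the real split and at most 851 in the others of 100 drawn, and XEN Wnt3a against PrES 6531 and at most 3 of 84. In both the share of splits that gave as many genes was under 0.05. Other splits mix cell types within a side, which widens the spread, so they do not show how many of the calls are true. The other 3 comparisons hold the 4 XEN libraries, which come from 2 lines and so are not independent, and their real splits follow the counting set as well. PrES against XEN gave 5069 and at most 0 in the others of 100 drawn, PrES CD-1 against XEN 4840 and at most 0 of 35, and XEN Wnt3a against XEN 4422 and at most 0 of 35. Whole lines allow 28, 15 and 10 splits, too few for a share under 0.05 in the last pair, and they were not fitted because the columns do not name the line.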
